A study of Cyanidioschyzon merolae strain 10D with 6 samples.

How the data were processed

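Poly(A) RNA of Cyanidioschyzon merolae 10D wild type and of the Cme(z)-1 mutant line was measured in 6 libraries, 3 per group. Per the labels' protocols, cells grew in liquid culture in an acidic mineral medium (pH 2.5 to 3.0) at 42 °C under constant white light of 80 µmol per square metre and second, and libraries were made with poly(A) enrichment and a kit that gives unstranded data. The deposited values are raw whole-number read counts, which the authors gave for 4984 genes (4743 nuclear, 207 plastid and 34 mitochondrial) and 5074 single TE copies in one table per library. Trim Galore and STAR are named in the submitters' processing notes without versions. The program that counted reads and its treatment of reads that map to several places are not given in the sources used here. Reads of repeated sequence could therefore have been shared, assigned by estimate or dropped, which bears on every TE copy and on genes with near-identical copies. Gene coordinates come from the deposited annotation of build ASM9120v1, per the file headers, and TE coordinates from a deposited annotation whose lines name EDTA and which carries no header. Both use coordinates counted from 1. Gene models have a single exon in 4982 of 4984 cases and hold no untranslated regions, so their lengths are coding lengths. Without strand, reads of a gene, of an antisense transcript and of an overlapping TE copy cannot be told apart. Of the genes 491 overlap a TE copy, and of the TE copies 517 overlap a gene.

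A table of locus tags and symbols for the assembly ASM9120v1 matched 4731 genes, and its symbols repeat the locus tags. The gene annotation names 96 genes, all of the plastid. All other genes are given by identifier. CMQ156C was taken as the E(z) gene from published knowledge of this alga, fixed before the data were examined, as were the groups, the tests, the gene lists, the named-gene rule and the alternatives. Groups and replicate numbers come from the sample titles. The titles give one mutant line, and nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical, and a trait of this line other than the loss of E(z) goes with the group. Every pair of libraries within a group differed by more than counting noise (chi-square per degree of freedom 18.3 to 38.2 over at least 6810 rows), so no library was counted as a repeat of another.

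Differences were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Low rows were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and mutant and wild type were compared with glmQLFit and glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method over 4865 genes and 2776 TE copies together, and an adjusted p under 0.05 was called. The common biological coefficient of variation was 0.167. Levels are CPM over the TMM-scaled library sizes, as mean ± SD. Standard errors of log2 fold changes were taken from the F statistic. Where all libraries of a group had 0 counts, the fold is a bound against 3 counts per library; where they held 1 to 3 counts at most, the ratio of summed counts is given with an exact binomial interval of 95%. Location tests were two-sided Fisher exact tests over tested nuclear genes or TE copies. Distance to a chromosome end was counted from position 1 at the left and from the last annotated base at the right; the first annotated base of the 20 nuclear chromosomes lay between 212 and 1682. Lists were tested with limma 3.58.1 on log2 CPM (prior count 2), by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. Neighbouring calls were compared with 10000 random placements. Shares of counts were compared with exact permutation tests.

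Named by rule were E(z) and its 3 annotated neighbours on each side, other PRC2 subunits by product, and, among called genes with all libraries of one group above all of the other and a mean of at least 1 CPM in the higher group, the 10 largest rises and the 10 largest falls. For TE copies the same rule took up to 5 each way, and for lists of gene products up to 4 members of lowest p.

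The edgeR step was tested on simulated counts drawn from the means and library sizes of these libraries for 7641 rows. Of simulated genes changed 1.5-fold, 2-fold and 4-fold it recovered 52.2%, 88.1% and 100%, and of simulated TE copies 12.1%, 46.0% and 86.2%; 6.99% of all its calls were false, against 10.7% for DESeq2 and 4.98% for limma voom. Low counts of most TE copies thus limit the calls to large changes. Alternatives tried were median-ratio scaling, total counts alone, scaling on nuclear genes, no low-count filter and a strict one of 10 counts in every library of a group, DESeq2 1.42.0, limma voom, a test against a 2-fold change, the replicate number as a block, each library left out in turn, other distances from the chromosome end, other definitions of TE overlap, and other denominators of the shares. Alternatives added after seeing the data left out TE copies within 500 bp of a gene or within 5 kb of a changed gene, or thinned all libraries to 7860491 counts. GC content and sequence likeness between copies were not analysed here.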

Results

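Cyanidioschyzon merolae strain 10D is a unicellular red alga of acidic hot springs with a compact nuclear genome of 20 chromosomes. Poly(A) RNA was sequenced from 3 wild-type samples and 3 samples of Cme(z)-1, a mutant line without function of Polycomb Repressive Complex 2 (PRC2). The E(z) protein is the catalytic subunit of PRC2, which places a repressive methyl mark on histone H3. The comparison asked which gene transcripts and which transposable element (TE) transcripts differ between cells with and without this complex. Raw read counts were given for 4984 annotated genes and for 5074 single TE copies. The wild-type libraries held 9188335, 8182485 and 7860491 counts, and the mutant libraries held 10754544, 8292567 and 10089859. The first principal component of the scaled log values held 51.4% of the variance and separated the groups.

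The E(z) gene was read in every wild-type library and in no mutant library. The locus CMQ156C lies on chromosome 17 from 379207 to 381546 on the plus strand of build ASM9120v1, in a single coding exon. It had 1776, 1533 and 1770 counts in the wild-type libraries, or 206 ± 15.4 CPM (counts scaled to a common library size with TMM factors, SD, n = 3). It had 0 counts in each of the 3 mutant libraries, which allows up to 0.362 CPM, before TMM factors, in the shallowest of them. Against a floor of 3 counts per library the transcript was at least 671-fold lower in the mutant (edgeR quasi-likelihood test, adjusted p = 9.2e-07). Among its 3 annotated neighbours on each side, CMQ158C on the downstream side fell from 90.2 ± 9.51 to 47.6 ± 3.58 CPM (log2 fold change -0.92, SE 0.12, adjusted p = 0.0024). The other 5 neighbours did not pass the test. Their log2 fold changes were 0.075 for CMQ153C, -0.041 for CMQ154C, 0.35 for CMQ155C, -0.15 for CMQ159C and 0.24 for CMQ160C, and that of CMQ154C turned positive (0.016) when libraries were scaled by total counts alone.

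Close to the E(z) gene 2 Gypsy-type copies of the repeat family rnd-1_family-15 rose. TE_homo_3491 (377934 to 378332) had 1 count over the 3 wild-type libraries and 65, 43 and 59 counts in the mutant libraries, a ratio of 139 with a 95% counting interval of 24.5 to 5507. TE_homo_3492 (378325 to 378580) likewise had 1 wild-type count, against 106, 99 and 114 counts in the mutant, a ratio of 265 with a counting interval of 47.2 to 10490. On the downstream side the Copia-type copy TE_homo_3493 (381743 to 383084), singled out after its values were seen, fell from 5.37 to 2.04 CPM (log2 fold change -1.38, SE 0.32, adjusted p = 0.043 in the edgeR test). Counting intervals and floors cover counting error only, since the reads carried no molecular identifiers.

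**Figure D1:**
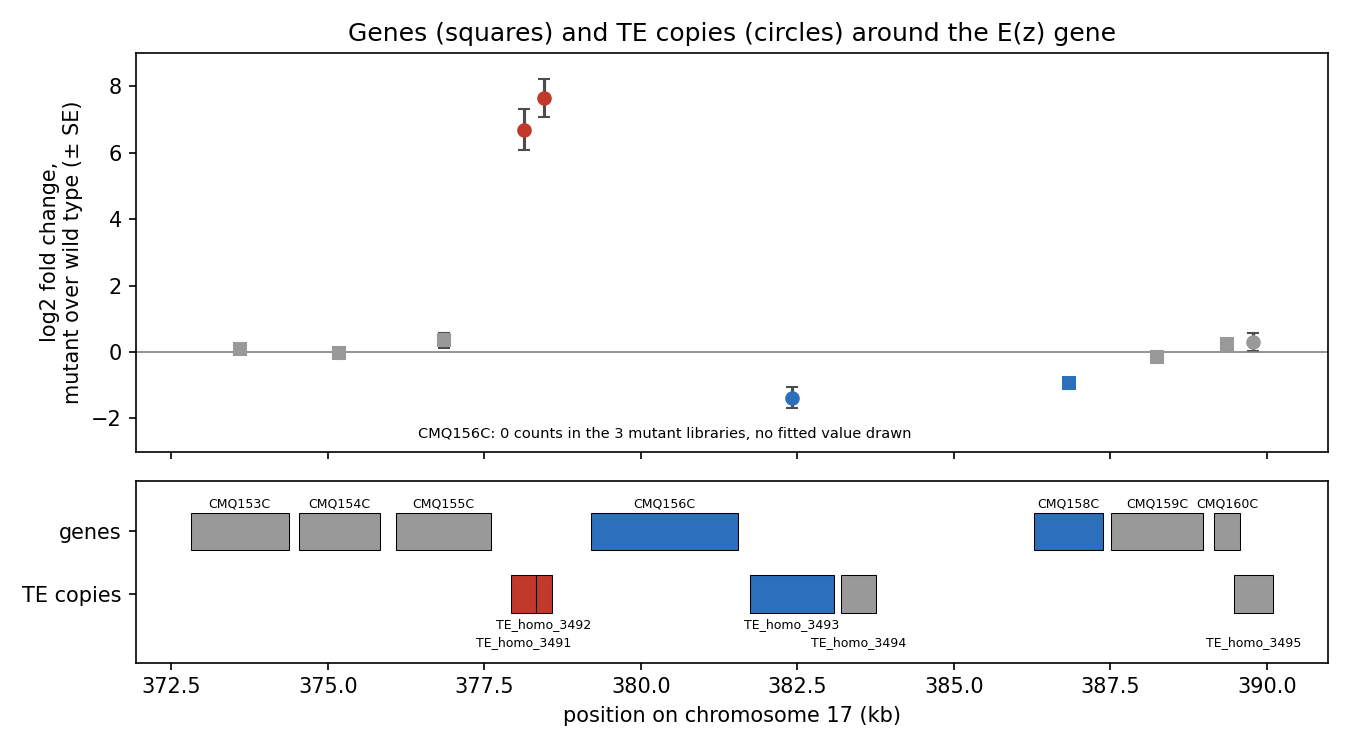
Log2 fold change (mutant over wild type, with its standard error from the edgeR fit) of the tested genes and TE copies along chromosome 17 around CMQ156C, above a map of the annotated features in kilobases. Red features rose, blue features fell and grey features did not pass the test or were not tested; TE_homo_3491 and TE_homo_3492 stand at 6.69 and 7.64, values fitted to a single wild-type count each.

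In the mutant 63 genes rose and 89 fell, of 4865 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 over genes and TE copies together). A change of 2-fold or more was seen for 37 of the raised and 19 of the lowered genes. The 10 largest rises all lay within 20 kb of an end of a nuclear chromosome. CMT003C (chromosome 20, 3520 to 5401) rose from 4.30 ± 0.865 to 179 ± 21.7 CPM (log2 fold change 5.38, SE 0.17, adjusted p = 5.1e-07). CMS002C, at the same positions of chromosome 19, had 3, 3 and 1 counts in the wild-type libraries and 280, 269 and 329 in the mutant libraries, a ratio of 104 with a 95% counting interval of 50.3 to 260 (adjusted p = 1.1e-05). CMP358C (chromosome 16, 902164 to 904479) rose from 20.8 ± 8.45 to 629 ± 99.7 CPM (log2 fold change 4.93, SE 0.31). CMD191C (chromosome 4, 507324 to 510080) rose from 7.63 ± 0.986 to 225 ± 29.6 CPM (4.88, SE 0.16), and CMD002C, at the opposite end of that chromosome (3379 to 6664), from 43.5 ± 16.4 to 419.6 ± 33.6 CPM (3.27, SE 0.24). CMR001C (chromosome 18, 3368 to 6125) went from 9.52 ± 1.02 to 143 ± 19.8 CPM, CMB162C (chromosome 2, 450845 to 453631) from 13.9 ± 5.01 to 191 ± 6.29, and CME001C (chromosome 5, 3352 to 6058) from 23.4 ± 8.47 to 213 ± 35.9. CMC188C (chromosome 3, 476222 to 477286) went from 38.4 ± 12.03 to 335 ± 44.6 CPM and CMA142C (chromosome 1, 409272 to 412007) from 30.0 ± 4.25 to 238 ± 37.1. Adjusted p for these 8 further genes was at most 9.3e-05. Of the 10 genes, 8 overlap an annotated TE copy over 37.6% to 100% of their length, and several have nearly the same length as another. Reads of near-identical copies cannot be assigned with certainty here, so the level of each single gene in this group is uncertain.

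After CMQ156C itself, the largest fall was that of CMI166C (chromosome 9, 460593 to 460989), which went from 12.3 ± 3.01 to 0.580 ± 0.443 CPM (log2 fold change -4.45, SE 0.47, adjusted p = 8.2e-04). CMK034C (chromosome 11, 87079 to 88228) fell from 314 ± 48.1 to 37.6 ± 7.56 CPM (-3.06, SE 0.17, adjusted p = 1.9e-05) and CMM069C (chromosome 13, 150144 to 152396) from 380 ± 63.4 to 58.8 ± 12.4 CPM (-2.69, SE 0.18, adjusted p = 5.0e-05). CMI002C, the terminal gene of 1 end of chromosome 9 (3447 to 5349), fell from 189 ± 64.9 to 33.5 ± 2.87 CPM (-2.50, SE 0.25, adjusted p = 6.1e-04), in the opposite direction to the raised terminal genes. Its length (1903 bp), strand and position are close to those of the raised CMS002C and CMT003C (1882 bp each). Reads moved between such genes could be part of this fall and of those rises. Their sequences were not analysed here. CMO185C on chromosome 15 fell from 240 ± 19.1 to 51.1 ± 7.46 CPM, CMK215C on chromosome 11 from 238 ± 29.7 to 68.0 ± 6.34, and CMH192C on chromosome 8 from 101 ± 40.3 to 29.1 ± 7.13. The neighbouring pair CMJ309C and CMJ308C on chromosome 10, both covered in full by TE annotation, went from 13.6 ± 2.71 to 2.82 ± 0.507 and from 13.3 ± 1.09 to 3.87 ± 0.713 CPM. Adjusted p of these last 5 genes lay between 1.9e-05 and 0.0078. Of the called genes 41.4% were raised, a share that became 56.95% when libraries were scaled by total counts alone and 53.9% when the scaling used nuclear genes only. Without wild-type replicate 1 only 65 genes were called, without mutant replicate 1 only 73, DESeq2 called 326 and a test against a 2-fold change called 24.

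**Figure D2:**
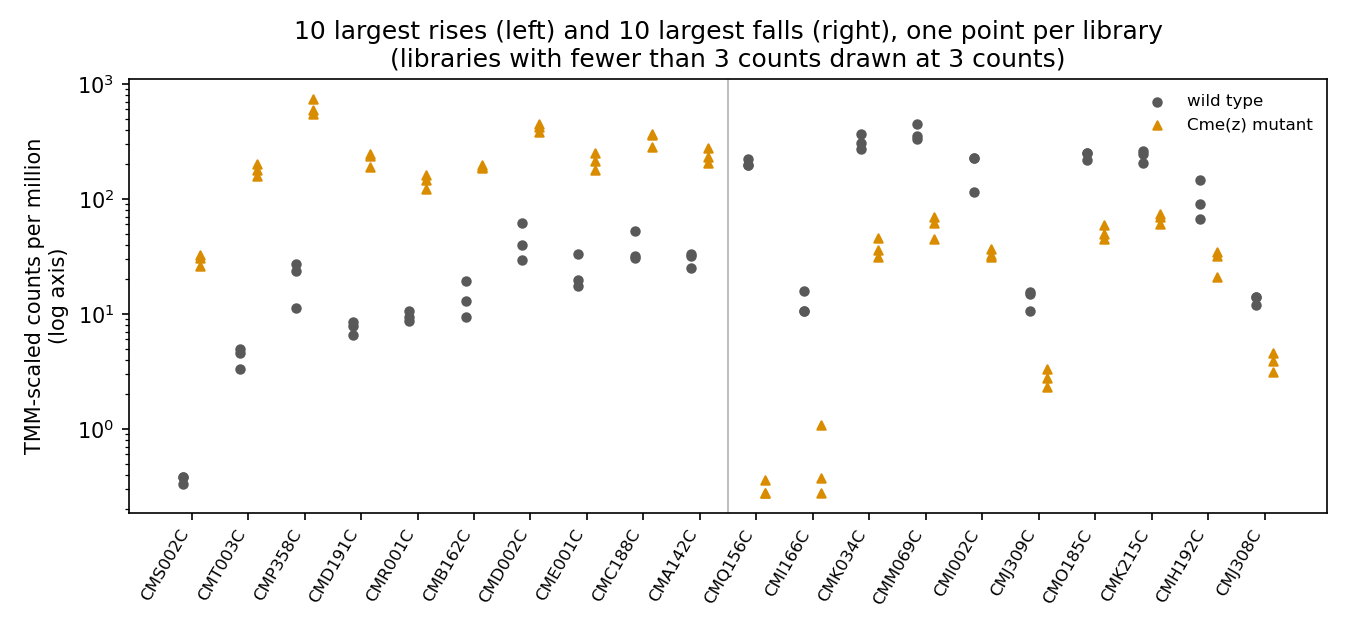
TMM-scaled CPM (log axis) of the 10 genes with the largest rise and the 10 with the largest fall, one point per library, circles for wild type and triangles for the mutant. Libraries with fewer than 3 counts are drawn at 3 counts; by the rule that chose these genes, the 3 mutant libraries lie on one side of the 3 wild-type libraries in each.

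TE transcripts changed mostly upwards. Of 2776 tested TE copies 197 rose and 29 fell in the same edgeR test, and 177 of the raised and 21 of the lowered copies changed by 2-fold or more. The largest fitted rise was in TE_homo_2, a Gypsy-type copy of chromosome 1 (11310 to 13794), from 2.18 ± 0.155 to 728 ± 67.8 CPM (log2 fold change 8.37, SE 0.17, adjusted p = 3.4e-08). TE_homo_562, a Gypsy-type copy at a like distance from the end of chromosome 5 (11276 to 13921), rose from 2.75 ± 0.890 to 508 ± 67.3 CPM (7.54, SE 0.22, adjusted p = 4.6e-07). TE_homo_924, Gypsy-type, near the end of chromosome 6 (533453 to 534027), had 0 counts in every wild-type library and 45, 24 and 53 counts in the mutant libraries, which makes it at least 10.95-fold higher against the floor of 3 counts per library (adjusted p = 0.0023). TE_homo_3492 and TE_homo_3491 beside the E(z) gene complete the 5 largest rises by fitted value. The fitted values of these 2 copies and of TE_homo_924 rest on 0 or 1 wild-type counts, so their place among the 5 is uncertain. The counting interval of TE_homo_3492 (47.2 to 10490) spans the 334-fold rise of TE_homo_2. Among the falls, the adjoining copies TE_homo_4342 (Harbinger) and TE_homo_4341 (Gypsy) of chromosome 19 went from 111 ± 15.4 to 13.4 ± 2.11 CPM and from 217 ± 3.19 to 30.4 ± 3.64 CPM. TE_homo_1851, a Copia-type copy of chromosome 11 at 85001 to 86347, close to the lowered gene CMK034C, fell from 124 ± 21.7 to 19.7 ± 1.84 CPM. Adjusted p of these 3 copies was at most 1.9e-05. TE_homo_1332 at the end of chromosome 9 (215 to 3339), next to the lowered CMI002C, fell from 13.9 ± 6.78 to 2.65 ± 0.653 CPM (adjusted p = 0.015), a call that was lost without wild-type replicate 1 (adjusted p = 0.065), mutant replicate 1 (0.070) or mutant replicate 3 (0.054). TE_homo_4173 of chromosome 19 had 11, 11 and 9 counts in the wild type and 0, 0 and 2 in the mutant, a wild-type to mutant ratio of 18.7 with a counting interval of 4.75 to 161 (adjusted p = 0.025). It passed in no run with 1 library left out: adjusted p was 0.070 without wild-type replicate 2, 0.064 without wild-type replicate 3 and 0.080 without mutant replicate 2, and in the other 3 runs it fell below the low-count filter.

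By class, 104 of 1508 long terminal repeat (LTR) copies rose and 15 fell, 77 of 1140 DNA-type copies (Helitrons included) rose and 12 fell, and 16 of 110 LINE copies rose and 2 fell. The LINE counts equal those of 2 repeat families together, rnd-1_family-24 (14 of 43 raised, 2 lowered) and rnd-1_family-25 (2 of 67 raised, 0 lowered). By these counts most raised LINE copies belong to rnd-1_family-24. None of 12 tested copies of unknown class passed in edgeR, where 1 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. Within the LTR class the Gypsy and Copia superfamilies differed, a comparison chosen after seeing the data. Of 447 Gypsy copies 64 rose (14.3%) and of 968 Copia copies 39 rose (4.03%), an odds ratio of 3.98 with a 95% interval of 2.58 to 6.20 (two-sided Fisher exact test, p = 3.8e-11, adjusted p = 7.5e-11 over 2 tests). With subtelomeric copies left out the odds ratio was 3.96 (2.38 to 6.70). The Copia family rnd-1_family-5 alone held 858 of the 968 tested Copia copies and 29 of the 39 raised ones. The contrast thus rests largely on that family, and was not tested with the family left out. The test also counted copies as separate, though copies of a family may share reads. Counts summed over all copies of each repeat family, also added after seeing the data, keep reads shared between copies in one row. Of 156 families tested in this way 7 rose and none fell at an adjusted p under 0.05, and 3 families were lower at an unadjusted p under 0.05 (edgeR). Adjusted p-values were taken over families and genes together, so the number of raised families depends on that choice. Only 83 of the 156 hold 2 or more copies, and 6 of these rose. In the others the sum is that of a single copy. The summed counts of the Gypsy family rnd-1_family-11 (50 copies) rose from 570 ± 32.7 to 1461 ± 68.2 CPM (log2 fold change 1.36, SE 0.13, adjusted p = 4.0e-04). Most of this gain came from 1 copy, TE_homo_2, which went from 2.18 to 728 CPM. This family was 1 of 2 raised among 19 Gypsy families, and of 12 Copia families 1 rose, rnd-1_family-62 (2.20, SE 0.23, adjusted p = 8.1e-04). With so few raised families, a comparison of their numbers (Fisher exact p = 1) could not decide whether the superfamilies differed in summed counts. The larger Gypsy families rnd-2_family-22 (adjusted p = 0.12), rnd-1_family-9 (0.43) and rnd-1_family-15 (0.45) did not pass. Gene models here hold no untranslated regions, and 2731 of the 5074 TE copies lie within 500 bp of a gene. With those copies left out 83 copies were raised and 14 lowered. Without wild-type replicate 1, 124 copies were raised and 11 lowered.

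The share of all counts that fell in TE copies was 9.22% ± 0.165 (SD, n = 3) in the wild type and 10.5% ± 0.794 (n = 3) in the mutant. The mutant libraries all lay above the wild-type libraries, with a difference of 1.31 percentage points and a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. The difference was 0.856 points without mutant replicate 2. Plastid and mitochondrial genes together took 0.907% ± 0.0905 of counts in the wild type and 1.01% ± 0.192 in the mutant (n = 3 each, two-sided exact permutation p = 0.4), with overlapping values between the groups.

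Raised genes were concentrated at chromosome ends. Of 169 tested nuclear genes within 20 kb of position 1 or of the last annotated base of a chromosome, 20 rose (11.8%), against 41 of 4508 other nuclear genes (0.909%). The odds ratio was 14.6 with a 95% interval of 7.90 to 26.2 (two-sided Fisher exact test, p = 8.1e-15, adjusted p = 4.1e-14 over 10 location tests). Location tests count each gene or TE copy as separate. Yet 10 of the 20 raised subtelomeric genes had a length within 3% of another raised one and may share reads. Others may share reads with genes that were not raised. The raised CMC188C, for example, has the length (1065 bp) of CMA145C and CMI306C, which were not called. Intervals and p-values of these tests may therefore overstate the certainty. For lowered genes the shares were 3 of 169 and 84 of 4508, and the test did not pass (odds ratio 0.952, 0.190 to 2.93, Fisher exact p = 1). Within 5 kb of an end 13 of 36 tested genes rose (36.1%, 95% exact binomial interval 20.8 to 53.8), between 5 and 10 kb 1 of 28, between 10 and 20 kb 6 of 105, and beyond 100 kb 28 of 3630 (0.771%, 0.513 to 1.11). The outermost annotated gene was tested at 38 of the 40 chromosome ends; 13 of these genes rose and 1, CMI002C, fell. TE copies were tested in the same way after seeing the data. Of 152 subtelomeric TE copies 55 rose (36.2%), against 142 of 2615 elsewhere (5.43%), an odds ratio of 9.86 (6.66 to 14.5, Fisher exact p = 1.8e-27, adjusted p = 1.8e-26). At 29 of the 40 ends at least 1 gene or TE copy within 20 kb rose. Counting only genes without TE overlap, the odds ratio for raised genes was 6.89 (Fisher exact p = 1.9e-04). With TE-overlapping genes included, the odds ratio for raised genes was 27.1 within 10 kb and 6.96 within 40 kb.

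**Figure D3:**
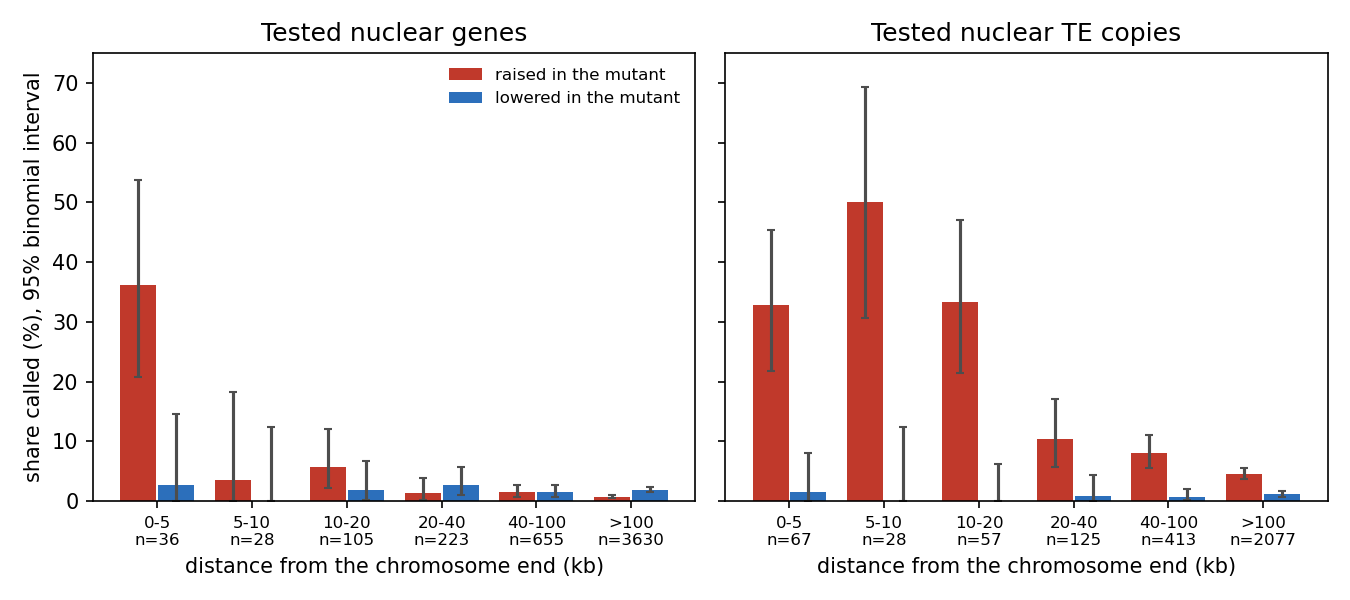
Share of tested nuclear genes (left) and TE copies (right) that were raised or lowered in the mutant, in percent with 95% exact binomial intervals, by distance in kilobases from the chromosome end. Within 5 kb of an end 36.1% of genes and 32.8% of TE copies rose, against 0.771% and 4.62% beyond 100 kb; the bins hold different numbers of rows, printed under each.

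Genes that overlap an annotated TE copy also rose more often. Of 360 such tested nuclear genes 20 rose (5.56%), against 41 of 4317 others (0.950%), an odds ratio of 6.13 with a 95% interval of 3.36 to 10.8 (two-sided Fisher exact test, p = 1.1e-08, adjusted p = 3.5e-08). With subtelomeric genes left out the odds ratio was 2.71 (Fisher exact p = 0.024), with 7 raised genes in the group. Counting all genes within 1 kb of a TE copy it was 2.07 (Fisher exact p = 0.016). For lowered genes the counts were 3 of 360 against 84 of 4317, and the test did not pass (odds ratio 0.424, 0.0852 to 1.29, Fisher exact p = 0.16). Of 2540 genes that lie within 1 kb of a TE copy without overlap, 27 rose and 42 fell, and neither test against the other genes passed (Fisher exact p = 0.12 and 0.28).

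Among the fixed lists, 11 had at least 2 tested members, and 6 of them passed camera with a preset correlation of 0.01, adjusted over the 11 lists. None of the 6 passed camera with an estimated correlation between genes, whose adjusted p is given second for each. Subtelomeric genes were higher as a group (20 of 169 raised and 3 lowered over all rows tested, 23 raised and 6 lowered adjusted over the list alone; median log2 fold change 0.086, adjusted p = 8.1e-04 and 0.18). Plastid-encoded genes were also higher (median 0.18, adjusted p = 0.0016 and 0.66), with 2 of 186 raised, 2 lowered and 182 not passing; 1 raised and 2 lowered passed adjusted over the list alone. The lowered pair was rbcL (CMV013C) and rbcS (CMV014C), the large and small subunits of the carbon-fixing enzyme Rubisco. rbcL went from 163 ± 15.7 to 90.3 ± 7.46 CPM (log2 fold change -0.85, SE 0.11, adjusted p = 0.0026) and rbcS from 46.6 ± 6.25 to 26.3 ± 3.91 CPM (-0.83, SE 0.17, adjusted p = 0.022). The raised pair was CMV107C, from 65.2 ± 2.65 to 94.1 ± 11.6 CPM, and CMV122C, from 11.8 ± 2.08 to 30.2 ± 8.87 CPM. Plastid transcripts enter a poly(A) library in part only, and their share of counts overlapped between the groups. LTR, LINE and DNA copies (without Helitrons) were higher, with adjusted p of 0.011 and 0.53, of 0.023 and 0.49, and of 0.015 and 0.53, and with 125, 25 and 96 members raised, 24, 6 and 18 lowered, adjusted over the list alone. In the 2 families whose counts make up the LINE copies, the median log2 fold change was 0.34 (rnd-1_family-24) and 0.0035 (rnd-1_family-25). Genes near a TE copy were lower relative to the other rows, TE copies included (median -0.035, adjusted p = 0.024 and 0.32; 27 raised and 42 lowered, or 17 and 26 adjusted over the list alone), and their median turned to 0.024 with libraries scaled by total counts alone. The median was -0.036 over all tested nuclear genes and 0.067 over TE copies, so by its median this list was not lower than genes in general.

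With an estimated correlation the subtelomeric list had the smallest unadjusted p, 0.016. The test fry, which tests whether a list moves on balance in one direction, gave an adjusted p of 0.0044 for subtelomeric genes and passed no other list. Without mutant replicate 2, which had the highest share of TE counts, 1 list passed the camera test with the preset correlation, the subtelomeric genes (adjusted p = 9.3e-05). The plastid list did not pass without mutant replicate 1 (adjusted p = 0.22) or mutant replicate 2 (0.059), and the LINE list not without wild-type replicate 1 (0.097). The lists that did not pass were TE-overlapping genes (adjusted p = 0.20, with 26 raised and 6 lowered adjusted over the list alone), Helitron copies (0.32), copies of unknown class (0.71), mitochondrial genes (0.94, with 2 of 34 genes tested) and the neighbours of E(z) (0.71, median 0.017 and mean -0.074 with a test direction of lower, 1 lowered adjusted over the list alone). None of the 10 Helitron copies passed singly in edgeR, where 1 had an unadjusted p under 0.05, and DESeq2 called 1. None of the 2 mitochondrial genes passed in edgeR, DESeq2 or limma voom, with 0 at an unadjusted p under 0.05 in edgeR. The 18 lists fixed by product wording, histones, chromatin modifiers and cell cycle among them, had 1 measured member in all, since gene product names were not used here. That member, the plastid chaperone gene dnaK (CMV163C), had 5.24 ± 1.23 CPM in the wild type and 5.67 ± 2.40 in the mutant (adjusted p = 0.93). Other PRC2 subunits were not analysed here.

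Changed genes lay next to each other more often than random placement of the calls gave. Of 61 raised nuclear genes 6 pairs were direct neighbours, against a mean of 0.772 pairs in 10000 random placements (permutation p = 2e-04). Of 87 lowered nuclear genes 8 pairs were direct neighbours, against a mean of 1.60 (permutation p = 5e-04), and 1 of them was CMQ156C with CMQ158C. Raised pairs included CMN309C with CMN310C on chromosome 14 (log2 fold changes 1.12 and 1.30), CMK071C with CMK072C on chromosome 11 (0.78 and 1.19) and CMR153C with CMR155C on chromosome 18 (1.68 and 1.06). Lowered pairs included CMO184C with CMO185C on chromosome 15 (-1.01 and -2.23) and CMT162C with CMT163C on chromosome 20 (-1.31 and -1.11); these pairs were singled out after their values were seen. With subtelomeric genes left out there were 4 raised pairs (permutation p = 6e-04) and 8 lowered pairs (p = 3e-04). Genes are not replicates, so these values describe the placement of the calls in these libraries. The data are unstranded and the gene models hold no untranslated regions. Reads of a transcript may thus also be counted in a close neighbour, which was not tested. CMK071C and CMK072C, for example, lie together between 213682 and 215215.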

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

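The tests that leave out TE copies near genes and the thinned libraries were chosen after seeing the data. The rise of subtelomeric and of TE-overlapping genes kept its direction and passed the Fisher test under every alternative run, with odds ratios of 6.89 to 62.5 and of 2.07 to 27.1. E(z) stayed at least 641-fold lower in each. The totals of called genes and TE copies stayed within 1.5 times under both other low-count filters, the other scalings, limma voom, the replicate block, thinning and, for TE copies, without those that overlap genes. DESeq2 called 326 genes (115 raised, 211 lowered) and 341 TE copies (70 lowered), against 152 (63 and 89) and 226 (29 lowered) in edgeR; all 152 genes were shared. Against a 2-fold change 24 genes (16 raised, 8 lowered) and 90 TE copies (84 raised, 6 lowered) were called, a stricter question by construction. Adjusting over TE copies alone gave 47 lowered ones. Without copies within 500 bp of a gene 97 were called (83 raised, 14 lowered) and without those within 5 kb of a changed gene 17 were lowered, from fewer copies tested. Leaving out 1 library at a time gave 65 to 144 genes (35 to 61 raised, 30 to 92 lowered) and 135 to 200 TE copies (124 to 179 raised, 11 to 26 lowered); fewer libraries lower the power, and the lowest counts came without wild-type replicate 1 (65 genes, 135 copies) and mutant replicate 1 (73 and 153). Lowered TE copies numbered 19 without mutant replicate 3 and 13 without mutant replicate 1. Replicate numbers do not pair the libraries by the rule set beforehand: deviations of same-numbered libraries correlated at 0.022, 0.135 and 0.259, and 4 of 6 libraries correlated best with their own number. The second principal component (18.4% of variance) nevertheless ordered the replicates alike in both groups. It was 4.25, 17.7 and -13.9 for wild-type replicates 1, 2 and 3, and -2.45, 20.8 and -26.4 for the mutant ones. A shared effect of the replicate number is therefore not excluded. With the replicate block 118 genes and 200 TE copies were called, and 18 copies were lowered. The number of lists past camera went from 6 to 0 with an estimated correlation and to 1 with fry, and lay between 1 and 6 with 1 library left out, 1 being the value without mutant replicate 2.

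The share of counts in TE copies differed by 0.856 to 1.55 percentage points, and that of organelle genes by 0.04755 to 0.218, with 1 library left out. Values that did not pass in any setting changed direction in some, and the cause was not tested. For lowered subtelomeric genes the odds ratio was 1.01 with limma voom, 3.83 against a 2-fold change, 1.27 within 40 kb and 1.19 without TE-overlapping genes, and for lowered TE-overlapping genes 1.72 against a 2-fold change and 0.497 to 1.38 with 1 library left out. The log2 fold change of CMQ154C was 0.016 with total counts, 0.011 with nuclear scaling and -0.11 to 0.025 with 1 library left out, and that of dnaK (CMV163C) was -0.28 to 0.33 with 1 library left out. The adjusted p of lists that turned direction with 1 library left out was 0.63 to 0.95 for mitochondrial genes (turned without wild-type replicate 3 or mutant replicate 2), 0.29 to 0.99 for copies of unknown class and 0.33 to 0.95 for neighbours of E(z) (both turned without mutant replicate 3). Among the other named genes and TE copies, single calls were lost 12 times over all settings, 5 of them in TE_homo_4173 (0.073 with the replicate block), which got no value with the strict filter or without wild-type replicate 1, mutant replicate 1 or mutant replicate 3. At these depths changes under 2-fold in most TE copies were not detectable.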

Other observations

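Of the tests below, those on repeat families, plastid gene groups, extra copies of chromosome ends, low counts, shared reads, neighbouring genes, thinned libraries and the E(z) locus were chosen only after the result was seen. Repeat families differed in how many of their copies rose, with a Fisher exact test adjusted over 32 families. Given here are those of lowest adjusted p. In rnd-1_family-8 7 of 13 tested copies rose (odds ratio against all other copies 15.8, Fisher exact adjusted p = 1.0e-04), in rnd-1_family-24 14 of 43 (6.72, adjusted p = 1.0e-05) and in rnd-1_family-1, a TcMar family, 10 of 35 (5.46, adjusted p = 7.9e-04). By its counts rnd-1_family-24 gave most of the raised LINE copies, so it is not a separate result from the rise of that class. The largest family, the Copia family rnd-1_family-5, had 29 raised copies of 858 (0.365, adjusted p = 2.9e-06). Counts summed over the copies of these 4 families did not pass in edgeR: log2 fold change 0.26 (adjusted p = 0.65) for rnd-1_family-8, 0.45 (0.19) for rnd-1_family-24, 0.50 (0.12) for rnd-1_family-1 and 0.068 (0.92) for rnd-1_family-5. In the subtelomeres 21 of 64 Gypsy copies, 10 of 29 Copia copies and 13 of 25 Harbinger copies were raised, against 43 of 383, 29 of 937 and 30 of 483 in the chromosome interior; differences between places were not tested per superfamily.

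Among plastid genes grouped by symbol, no photosystem gene (18 tested), gene with a pet symbol (8, the cytochrome b6f genes and petJ), ATP synthase gene (6), ribosomal protein gene (27) or RNA polymerase gene (3) passed singly in edgeR, DESeq2 or limma voom. At an unadjusted p under 0.05 edgeR gave 3, 0, 0, 2 and 1 of them. No nuclear chromosome moved as a whole; the median log2 fold change of genes was -0.066 to -0.015 over the 20 nuclear chromosomes.

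Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 152 genes and the highest other 0, 226 TE copies against 2, 20 subtelomeric and 20 TE-overlapping genes in one direction against 0 and 0, and 8 neighbouring pairs against 0. In each of these the real split alone (1 of 10) gave as large a result. For lists in camera with the preset correlation the real split gave 6 and the highest other 5. At an unadjusted p under 0.05 edgeR gave 739 genes in the real split and 672 in the highest other, and 598 TE copies against 219.

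Subtelomeric genes and TE copies rose more often than others. A gain of 1 copy of the chromosome ends would put the median log2 fold change of all subtelomeric genes near 1, and it was 0.086 (95% bootstrap interval 0.036 to 0.125, 169 genes), which argues against that gain as the whole cause. For genes, low counts are argued against as well, since within 10 bins of nuclear genes by wild-type level the common odds ratio was 11.7 (6.14 to 21.6); above the median wild-type level it was 6.15 (1.11 to 22.7) from 3 raised of 81 subtelomeric genes, and the 16.9 above the median over all libraries leans on the rise itself. Near-identical genes that share all their reads evenly would have the same fold change. The 10 of 20 raised subtelomeric genes with a length within 3% of another one differed by more than their errors. The heterogeneity Q was 208 on 7 degrees of freedom, with CMA001C at 2.59 (SE 0.20) and CMD191C at 4.88 (SE 0.16). Only raised genes entered these length groups. Left out was CMI002C (1903 bp, log2 fold change -2.50), of nearly the length of CMS002C and CMT003C (1882 bp each). The test therefore cannot address reads moved from a lowered gene to a raised one. Like length does not show that genes are near-identical, and genes that share only part of their reads could differ too. Even sharing of part of the reads, an uneven spread of reads from a few genes and a rise of separate genes cannot be told apart. The gene sequences, needed for that, were not analysed here. Release of chromosome ends from PRC2 in the mutant may account for part of the rise at these ends, as a hypothesis that these counts cannot separate from a trait of the single mutant line. The histone H3 methyl mark at these ends in both groups and further mutant lines, not analysed here, would decide.

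TE copies rose far more often than they fell, and transcripts of raised genes that reach into them are a poor candidate source for most: 80.7% of the 197 raised copies (95% interval 74.5 to 86.0) had no raised gene within 5 kb, and for the 158 with a tested gene within 1 kb the median log2 fold change was 2.24 in the copies and 0.025 in that gene. Deeper mutant libraries are argued against too, with 7.5 raised copies per lowered one (4.97 to 11.8) after all libraries were thinned to the smallest total. Reads that only moved between copies would leave family sums level, which is argued against as the only cause in every family: of 83 families with 2 or more copies the sums of 6 rose and 0 fell, and TE_homo_2 alone (728 CPM in the mutant) exceeded the wild-type sum of its family rnd-1_family-11 (570 CPM), though which other copies of these 6 families rose stays open. Sums were above 0 in 29 of 30 families with a raised copy (median 0.23, 0.13 to 0.48) and in 37 of 53 with none, and without the 6 the medians differed by 0.083 (-0.024 to 0.19), so that in the other 24 families such moves and a rise of single copies cannot be told apart. Loss of PRC2 at TE copies is a hypothesis that no test here addressed, and the H3 methyl mark at these copies in both groups and further mutant lines, not analysed here, would decide.

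The 2 raised Gypsy copies just upstream of the E(z) gene had higher fold changes than the rest of their family. The lower of their log2 fold changes exceeded the highest among the 66 other tested copies of rnd-1_family-15 (4.60, SE 0.39, TE_homo_34) by 2.10, while the median of those copies was 0.086 and 7 of them rose. These 2 copies came to notice among the 5 largest rises, so their place above the family follows from how they were chosen, and the lower counting bound of TE_homo_3491, a log2 ratio of 4.62, is level with TE_homo_34. Transcripts of the altered locus or of introduced DNA and a release of these copies by loss of PRC2 cannot be told apart, since how the gene was disrupted was not analysed here; the sequence of the locus in the mutant would decide.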
